A study of Schizosaccharomyces pombe with 16 samples.

How the data were processed

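Polyadenylated RNA from fission yeast grown in rich medium at 30 °C to an OD600 between 0.4 and 0.7 was sequenced as stranded paired-end libraries on an Illumina HiSeq instrument, with 8 libraries pooled per lane. The 16 libraries came from 8 strains, WT and 7 rpb1 CTD mutants, with 2 biological replicates each, and were grouped by the strain label alone. The S2A strain is h+ and the others are h-, so any comparison of S2A with another strain carries both differences.

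The authors deposited 1 table of 7022 annotated features, with introns and antisense features left out. Reads were aligned with Bowtie 0.12.7 per the submitters' processing notes, while the genome build, the annotation version and the counting tool were not given in the sources used here. The deposited table gives read counts per feature and library, and these counts were the input for every test. It also gives, per the file headers, log2 RPKM values computed by the authors, a log2 fold change and an adjusted p-value from the authors' DESeq runs (version not given) for 10 pairs of strains, and a feature width in bases. The deposited log2 RPKM values were checked against the counts: at least 56.9% of features in each library returned the library's total within 0.1%, and that total lay 0.44 to 2.98% above the sum of the features' counts. Of the features, 6844 were named through the reference annotation by locus tag and 23 by a synonym, and 155 had no match. On the same strand, 283 features were overlapped over most of their length, so their reads may be shared. Coordinates are those of the deposited table.

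Depth ran from 18677921 to 31254978 reads per library, and replicates varied beyond counting error, with a chi-square per degree of freedom of 90.3 to 163.8. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Features were filtered with filterByExpr by strain, which left 6420, and scaled with TMM factors between 0.911 and 1.154. A quasi-likelihood model with robust spread had 1 coefficient per strain over all 16 libraries, leaving 8 residual degrees of freedom, a common dispersion of 0.0374 (a biological coefficient of variation of 19.3%) and a median of 3.7 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg (BH) adjustment over the features tested in each comparison, and a feature was called at an adjusted p under 0.05. Principal component 1 of log2 CPM held 41.6% of the variance, and component 2, with 13.2%, separated the replicate numbers.

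The comparisons were each of the 7 mutants with WT, each of the 3 double mutants with its parent, 3 interactions (the S7A effect in another mutant minus that in WT) and 1 joint test among the single mutants. The strains, comparisons, tests, alternatives, naming rule and 35 gene lists were fixed before the data were examined. Named by rule were the 6 highest and 6 lowest called features of each single mutant against WT and the 4 highest and 4 lowest of the other comparisons. These needed an average log2 CPM of at least 3 and, except for interactions, both libraries of the first strain beyond both of the second. The rule added up to 4 members with the smallest adjusted p of each list that was called or had at least 2 called features, and rpb1 with a fixed set of phosphate, iron, mating, marker and housekeeping genes in every strain. The text prints part of these. SPAPJ695.02 was added after its value was seen.

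The lists covered nutrient uptake, mating and meiosis, stress, translation, metabolism, chromatin, transcription and RNA classes. Of the 35, 33 had at least 3 tested features and were tested with camera at a preset correlation between genes of 0.01, with BH adjustment over the lists of a comparison. This called 54 of 231 tests against WT. With a correlation estimated from the data camera called 0 without the replicate block. With the block it called proteasome genes in Y1F and Y1F-S7A alone (adjusted p = 0.00653 and 0.0176), so the other list calls rest on the preset value. The fry test, which asks whether a list's features move one way and compares no list with other features, called 28. A list's median, mean and test differed in sign for some lists with few or no calls, such as thiamine genes in Y1F (median -0.09, mean 0.14, tested lower), zinc genes in S2A (median 0.09, mean -0.41) and flocculin genes in T4A (median 0.07, mean -0.09).

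Alternatives were RLE factors in place of TMM, no low-count filter, the replicate number as a block, only the libraries of the strains compared, a fold minimum of 2, DESeq2 1.42.0 and each library left out in turn. With a library left out its strain has 1 library, which is then assumed to vary like the other strains. Pseudocounts were planned for normalized values and do not apply to counts. The method was tested on simulated data in which 200 features of the Y1F libraries were changed. In the comparison of Y1F with WT it recovered 8% of features changed 1.5-fold, 53.1% at 2-fold, 82% at 4-fold and 87.8% at 8-fold. With the block it recovered 46%, 85.7%, 86% and 98%, and 4.3% of its calls were on unchanged features. The simulated counts were drawn from the blocked fit, with the same replicate effect in all strains. The block thus holds there by construction, and these shares do not test it on the real libraries. For an interaction the shares at these folds were 0%, 14%, 60% and 91.8%, so changes under 2-fold were mostly out of reach there. Correlations and covariances between mutants were set against 15 simulated draws of unchanged groups tested against the same WT libraries. These draws give no baseline for the number of shared calls. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.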

Results

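The libraries measured polyadenylated RNA, strand by strand, in fission yeast whose RNA polymerase II carried substitutions in the carboxy-terminal domain (CTD) of its largest subunit, Rpb1. The CTD is a tail of repeated heptads, and each strain name gives the replaced residue: tyrosine by phenylalanine in Y1F, serine by alanine in S2A and S7A, and threonine by alanine in T4A. There were 16 libraries from 8 strains with 2 biological replicates each. The strains were wild type (WT), the 4 single mutants, and 3 double mutants that combined S7A with 1 of the others. Summed counts ran from 18677921 to 31254978 reads per library. Of 7022 annotated features, 6420 passed the low-count filter and were tested. Levels are given as CPM (counts scaled to library size) ± SD and changes as log2 fold change ± SE, with n = 2 libraries per strain. Rose and fell are used of features past an adjusted p of 0.05 in edgeR's quasi-likelihood test with BH adjustment. Highest and lowest by rule are taken among called features with an average log2 CPM of at least 3 and, except for interactions, both libraries beyond both of the other strain, so features outside this limit can have larger changes.

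Libraries that shared a replicate number also shared deviations from their strain means, with correlations across features of 0.24 to 0.67 over the 28 pairs of strains (features are not independent replicates). In a fit with the number as a block, 3228 features differed between the numbers, 1596 higher and 1632 lower in number 2. The fit with the block called more features in each of the 14 comparisons, and its total is given beside that of each comparison. For gene lists and single genes its values are given in part.

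The mutated gene itself, rpb1 (SPBC28F2.12, chromosome II, 1591120 to 1596744), did not pass the test in any mutant. Its level was 311.2 ± 79.7 CPM in WT, 353.5 ± 13 in Y1F, 283.2 ± 27.6 in S2A, 290.5 ± 24.1 in T4A and 272.4 ± 24.3 in S7A. It was 293.5 ± 18.5 CPM in Y1F-S7A, 317.6 ± 41.7 in S2A-S7A and 216.3 ± 24.6 in T4A-S7A. The lowest of these, in T4A-S7A, was a change of -0.52 ± 0.18 (adjusted p = 0.19, and 0.025 with the block). None of ade6, leu1 and act1 passed the test in any mutant against WT, and ura4 had 0 reads in each of the 16 libraries, where the genotype lists a ura4 deletion. A count of 0 allows up to 3 reads per library, for counting error alone.

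**Figure D1:**
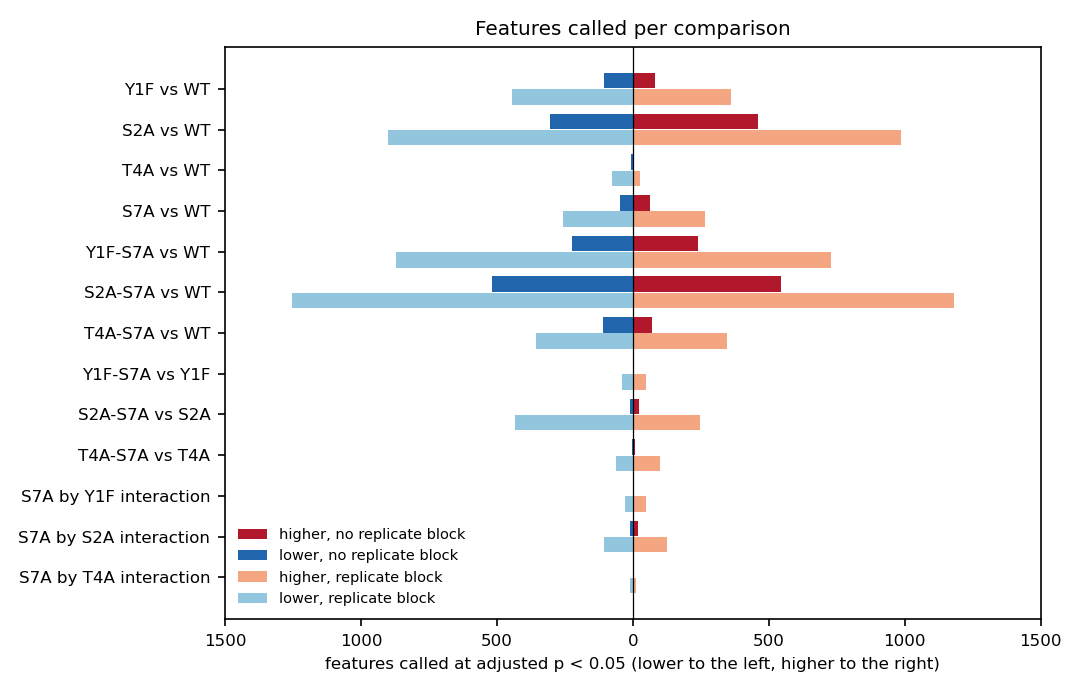
Features past an adjusted p of 0.05 per comparison, counted to the right where higher and to the left where lower, in the fit without (dark) and with (light) the replicate number as a block. Counts without the block ran from 0 for S7A by Y1F to 1061 for S2A-S7A against WT.

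The comparison of Y1F with WT asks which transcripts depend on the tyrosine of the heptad. Highest by rule were iron uptake genes, with str3 up by 6.62 ± 1.21 (adjusted p = 0.015), from 0.216 ± 0.241 to 22.2 ± 6.12 CPM, frp1 by 4.11 ± 0.57 (adjusted p = 0.003) and fip1 by 4.03 ± 0.58 (adjusted p = 0.0039), from 47.1 ± 7.73 to 768.2 ± 227.0 CPM. The increases of fio1, 3.93 ± 0.69 (adjusted p = 0.013), and str1, 3.40 ± 0.73 (adjusted p = 0.03, and 0.054 with the block), followed, and the non-coding RNA SPNCRNA.1613 rose by 2.98 ± 0.36 (adjusted p = 0.0021). The lowest by rule were SPBC1683.04 at -4.56 ± 0.37 (adjusted p = 0.00028), SPAC11D3.11c at -3.05 ± 0.32, SPAC11D3.10 at -2.98 ± 0.40, mal1 at -2.56 ± 0.32, urh1 at -2.47 ± 0.27 and hsp3104 at -2.39 ± 0.32. In all, 83 features rose and 107 fell (361 and 446 with the block). The count of 190 became 62 without WT replicate 1, 63 without WT replicate 2, 51 without Y1F replicate 1 and 69 without Y1F replicate 2. Of the 30 features named by rule and called here, 13 remained called without each of these libraries in turn, frp1, SPBC1683.04 and hsp3104 among them. The fip1 call was lost without WT replicate 1 (adjusted p = 0.055), the str3 call without WT replicate 1, WT replicate 2 or Y1F replicate 1 (adjusted p = 0.11, 0.086 and 0.069), the fio1 call without WT replicate 1, WT replicate 2 or Y1F replicate 2 (adjusted p = 0.093, 0.12 and 0.067), and the str1 call without each of the 4 (adjusted p from 0.089 to 0.19).

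Among the fixed gene lists in Y1F, 7 of 12 iron uptake genes rose, 1 fell and 4 did not pass (9 rose and 1 fell adjusted over the list alone). The list test called them higher (adjusted p = 2.39e-08, and adjusted p = 0.109 with an estimated correlation), and shu1, near 0 in WT at 0.0914 ± 0.129 CPM, was among them at 9.66 ± 7.80 CPM. Of 30 proteasome genes 2 rose, pre4 by 0.57 ± 0.11 and rpn7 by 0.54 ± 0.12 (5 adjusted over the list alone, 18 with the block), with a list median of 0.36 (adjusted p = 1.31e-10, and with an estimated correlation adjusted p = 0.109 without the block and 0.00653 with it). Of 25 core stress genes 3 rose, srx1 by 2.12 ± 0.30, obr1 by 1.52 ± 0.25 and atf1 by 0.67 ± 0.14 (11 higher and 1 lower adjusted over the list alone, 12 higher and 1 lower with the block, and adjusted p = 0.21 with an estimated correlation). The flocculin genes pfl7, pfl9 and pfl8 fell by 4.33, 1.65 and 0.81, as 3 of 11 (3 adjusted over the list alone, and adjusted p = 0.611 with an estimated correlation). The block took ght5, a hexose transporter at 2.77 ± 0.63 (adjusted p = 0.038), to an adjusted p of 0.052. Its change was 1.52 without Y1F replicate 1 (adjusted p = 0.3), and the call was also lost without WT replicate 1 or WT replicate 2 (adjusted p = 0.23 and 0.12). Of the called genes named in this paragraph, srx1 and pfl7 alone remained called without each library in turn. Of the phosphate genes, pho1 changed by -0.78 ± 0.19 (adjusted p = 0.054, and 0.0087 with the block) and pho84 by -1.08 ± 0.35 (adjusted p = 0.15, and 0.00017 with the block).

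**Figure D2:**
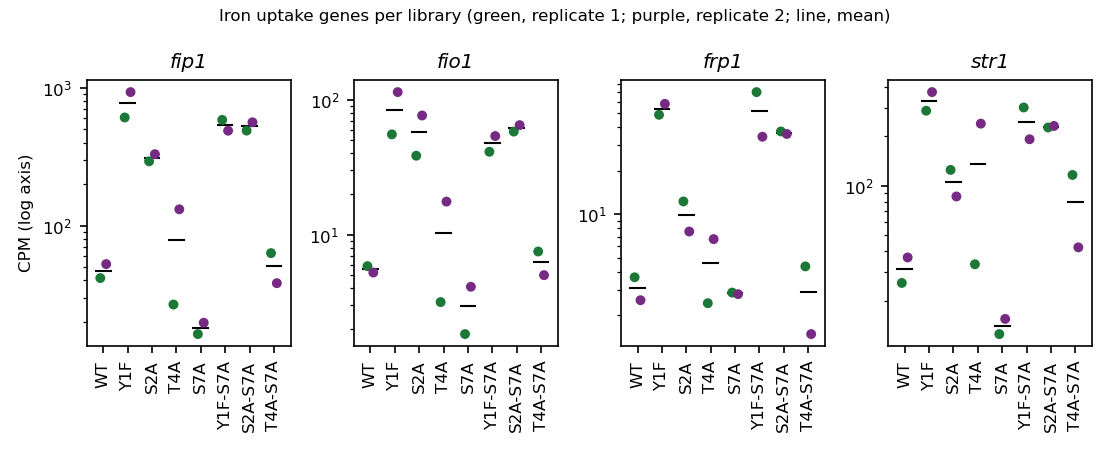
Levels of fip1, fio1, frp1 and str1 in CPM on a log axis in each library of the 8 strains (green replicate 1, purple replicate 2, line the mean). For fip1 the mean was 768.2 CPM in Y1F and 47.1 CPM in WT.

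The comparison of S2A with WT asks the same of the serine that S2A removes, in the 1 strain of the opposite mating type (h+, against h- in the other strains). Highest by rule were non-coding RNAs, with SPNCRNA.581 up by 4.94 ± 0.38 (adjusted p = 1.5e-05), SPNCRNA.803 by 4.81 ± 0.26, from 2.17 ± 0.219 to 60.8 ± 4.96 CPM (adjusted p = 2.5e-06), SPNCRNA.1613 by 4.54 ± 0.38, SPNCRNA.1271 by 4.42 ± 0.61, SPNCRNA.990 by 3.84 ± 0.28 and SPNCRNA.1273 by 3.74 ± 0.37. Lowest by rule were mfm2, a mating pheromone gene, at -4.61 ± 0.47 (adjusted p = 9.2e-05), SPBC23G7.10c at -4.53 ± 0.60, SPNCRNA.388 at -3.97 ± 0.80, SPNCRNA.1487 at -3.86 ± 0.24, SPNCRNA.1488 at -2.78 ± 0.26 and SPCC965.14c at -2.46 ± 0.27. For mfm2, SPBC23G7.10c, SPNCRNA.1487 and SPNCRNA.1488 the mating type and the substitution cannot be separated in this comparison, since the strain carries both. In S2A-S7A, which is h- and keeps the S2A substitution, they stood at -0.12, 0.90, -0.49 and -1.20 against WT, the last alone called. The S2A substitution alone would thus account for the first 3 falls only if S7A reversed its effect, which was not tested apart from mating type. In all, 460 features rose and 303 fell (986 and 900 with the block). The count of 763 became 428 without WT replicate 1, 418 without WT replicate 2, 379 without S2A replicate 1 and 473 without S2A replicate 2, and 26 of the 46 called features named by rule remained called without each library in turn.

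Of 1333 non-coding RNA features in S2A, 275 rose and 47 fell (327 and 64 adjusted over the list alone, 406 and 106 with the block), and the list test called them higher (adjusted p = 2.33e-08, and adjusted p = 0.451 with an estimated correlation). Iron uptake genes rose in 3 of 12 cases, fip1 by 2.72 ± 0.55, fio1 by 3.37 ± 0.68 and sib1 by 1.42 ± 0.33 (7 adjusted over the list alone, 6 with the block, and adjusted p = 0.451 with an estimated correlation). These calls were lost for fip1 without WT replicate 1 (adjusted p = 0.072), for fio1 without WT replicate 1 or WT replicate 2 (adjusted p = 0.059 and 0.07) and for sib1 without WT replicate 1, WT replicate 2 or S2A replicate 1 (adjusted p = 0.089, 0.089 and 0.14). Of 27 meiotic genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, and adjusted p = 0.451 with an estimated correlation). Among those that rose were rec10 at 2.02 ± 0.24, dmc1 at 3.01 ± 0.37, spn5 at 2.62 ± 0.35 and mde2 at 2.94 ± 0.49. Early mating genes went the other way, with byr1 at -1.25 ± 0.18, gpa1 at -1.36 ± 0.27, ste4 at -1.67 ± 0.36 and ste11 at -1.05 ± 0.28, or 4 lower and 0 higher of 14 (5 lower and 1 higher adjusted over the list alone, and adjusted p = 0.655 with an estimated correlation). Of these byr1 alone remained called without each library in turn, and ste11 stood at -0.53 without WT replicate 1 (adjusted p = 0.27). Of the genes specific to a mating type, 1 of 9 M-cell genes fell (1 lower and 1 higher adjusted over the list alone) and 1 of 5 P-cell genes rose (1 adjusted over the list alone). Both pho1, at -0.83 ± 0.19 (adjusted p = 0.014), and pho84, at -1.18 ± 0.35 (adjusted p = 0.05, just under the threshold), fell. The pho1 call was lost without WT replicate 1, S2A replicate 1 or S2A replicate 2 (adjusted p = 0.11, 0.095 and 0.074), and the pho84 call without each of the 4 libraries (adjusted p from 0.092 to 0.24). Single members of other lists included nmt1 at 3.49 ± 0.43, gst1 at -4.09 ± 0.42 and zrt1 at -1.88 ± 0.26. The 131 cytosolic ribosomal protein genes had a median of -0.35 with 1 gene lower, rpl1603 at -1.02 ± 0.23 (0 adjusted over the list alone, 9 with the block, and adjusted p = 0.658 with an estimated correlation).

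The comparison of T4A with WT asks the same of the threonine. The acid phosphatase gene pho1 (SPBP4G3.02, chromosome II, 4446373 to 4449053) fell by 2.96 ± 0.20 (adjusted p = 4.7e-05), from 1316 ± 164 to 168.7 ± 32.6 CPM. The deposited pho1 feature is 2681 bases wide, against 1548 for the reference gene. Every pho1 value given here may therefore include reads from outside the reference gene. The other features that passed were gnr1 at 1.38 ± 0.14 (adjusted p = 0.0016), SPNCRNA.888 at -2.56 ± 0.27 (adjusted p = 0.0016), abp2 at -0.87 ± 0.13 (adjusted p = 0.032), hsr1 at -0.67 ± 0.10 (adjusted p = 0.02) and SPAPJ695.02 at -2.55 ± 0.36 (adjusted p = 0.02), the last outside the naming rule and chosen after its value was seen. Thus 1 feature rose and 5 fell (28 and 77 with the block), while DESeq2 called 20 higher and 47 lower. The count of 6 became 2 without T4A replicate 1, 2 without T4A replicate 2, 4 without WT replicate 2 and 6 without WT replicate 1. Only pho1 and gnr1 remained called in each of these 4 fits. With the T4A and WT libraries alone 0 features were called, pho1 standing at an adjusted p of 0.06 and gnr1 at 0.45. An unadjusted p under 0.05 was seen for 492 features.

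Next to pho1 lies the phosphate transporter gene pho84 (SPBC8E4.01c, chromosome II, 4444125 to 4446200), which changed by -2.08 ± 0.36 in T4A, from 701.3 ± 118.0 to 166.1 ± 63.1 CPM (adjusted p = 0.073, and 1.2e-06 with the block). The 3 genes of the phosphate list thus gave 1 lower (2 lower adjusted over the list alone, and adjusted p = 0.106 with an estimated correlation), with tgp1 (SPBC1271.09, chromosome II, 350692 to 352369) at -0.53 ± 0.32 (adjusted p = 0.8). Non-coding RNA features had a median of -0.31 in T4A with 1 of 1333 lower (1 adjusted over the list alone, 7 higher and 42 lower with the block, and adjusted p = 0.106 with an estimated correlation). Iron uptake genes passed in 0 of 12 cases in T4A, with fip1 at 0.74 ± 0.52 (adjusted p = 0.87) and its libraries spread over 79.0 ± 73.9 CPM.

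**Figure D3:**
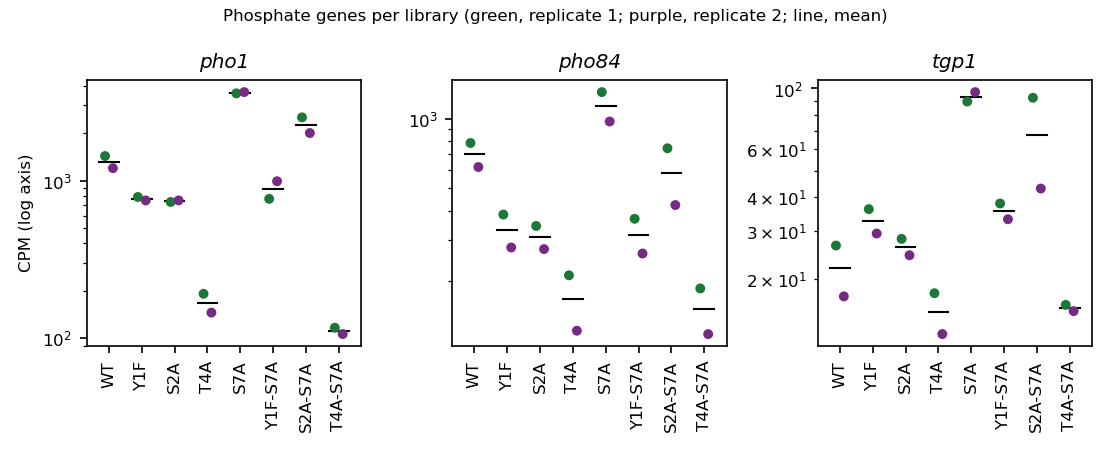
Levels of pho1, pho84 and tgp1 in CPM on a log axis in each library of the 8 strains (green replicate 1, purple replicate 2, line the mean). The pho1 mean was 168.7 CPM in T4A and 3609 CPM in S7A, on either side of 1316 CPM in WT.

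The comparison of S7A with WT asks the same of the serine that S7A removes. Of the phosphate genes, tgp1 rose by 2.09 ± 0.32 (adjusted p = 0.008), from 21.9 ± 6.56 to 93.3 ± 5.25 CPM. So did pho842 by 2.06 ± 0.30 (adjusted p = 0.0069), from 74.1 ± 14.3 to 309.5 ± 0.418 CPM. The pho1 increase was 1.46 ± 0.19 (adjusted p = 0.0064), from 1316 ± 164 to 3609 ± 46.4 CPM, while pho84, given below, did not pass. The calls of pho1, pho842 and tgp1 were lost without WT replicate 2, with pho1 at 1.34 and pho842 at 1.88. The tgp1 call was also lost without S7A replicate 1 or S7A replicate 2. Of the others the highest by rule were SPNCRNA.952 at 2.32 ± 0.23 (adjusted p = 0.0014), ppk31 at 2.31 ± 0.22 (adjusted p = 0.0014), SPNCRNA.875 at 2.26 ± 0.34 and SPNCRNA.1613 at 2.10 ± 0.36. By rule the lowest were gdt1 at -5.88 ± 0.81 (adjusted p = 0.0066), from 133.2 ± 5.47 to 2.17 ± 1.96 CPM, and nrg1 at -3.38 ± 0.58, followed by SPNCRNA.1672, SPNCRNA.1674, SPNCRNA.1618 and SPNCRNA.1340 between -1.94 and -1.82. SPNCRNA.1672 and SPNCRNA.1674 overlap on 1 strand and share reads. In all, 64 features rose and 46 fell (264 and 256 with the block). The count of 110 became 37 without WT replicate 1, 21 without WT replicate 2, 18 without S7A replicate 1 and 17 without S7A replicate 2, and 5 of the 23 called features named by rule remained called in each of these fits, SPNCRNA.1557, SPNCRNA.952, mei4, ppk31 and spn5.

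Of the 3 phosphate list genes in S7A 2 rose (2 adjusted over the list alone, 3 with the block, and adjusted p = 0.268 with an estimated correlation), while pho84 changed by 0.70 ± 0.35 (adjusted p = 0.48, and 0.0058 with the block). Of 27 meiotic genes 6 rose, among them mei4 by 1.78 ± 0.21, spn5 by 2.49 ± 0.35, spo6 by 2.25 ± 0.39 and spn6 by 2.91 ± 0.60 (11 adjusted over the list alone, 10 with the block, and adjusted p = 0.217 with an estimated correlation), and mei2 changed by 1.48 ± 0.42 (adjusted p = 0.13, and 0.0094 with the block). Of the 4 subtelomeric reporters 2 fell, gdt1 and SPAC186.06, the latter by 5.34 from a WT level of 7.64 ± 4.18 CPM (2 lower and 1 higher adjusted over the list alone). The SPAC186.06 call was lost without each of the 4 libraries (adjusted p from 0.065 to 0.26), with a change of -10.51 without S7A replicate 1, and the gdt1 call without S7A replicate 2 (adjusted p = 0.067). In the core stress list ecl1 fell by 1.31 and ctt1 rose by 0.86 (2 lower and 2 higher adjusted over the list alone), and the list's median of 0.32 lay far from its mean of 0.05. Iron uptake genes passed in 0 of 12 cases, with fip1 at -1.39 ± 0.53 (adjusted p = 0.3).

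A joint test across Y1F, S2A, T4A and S7A asks which transcripts differ among the single mutants at all. It called 1121 features (2874 with the block). Among the genes named above that it called were pho1 (adjusted p = 2.0e-06), pho84 (adjusted p = 0.00075), tgp1 (adjusted p = 0.00053), fip1 (adjusted p = 0.00027), frp1 (adjusted p = 0.00038), fio1 (adjusted p = 0.0016), mei2 (adjusted p = 0.0028) and SPNCRNA.803 (adjusted p = 1.0e-06). For rpb1 (adjusted p = 0.41), act1 (adjusted p = 0.45), ade6 (adjusted p = 0.46) and leu1 (adjusted p = 0.8) no difference was called. The count fell to 672 without S2A replicate 1.

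**Figure D4:**
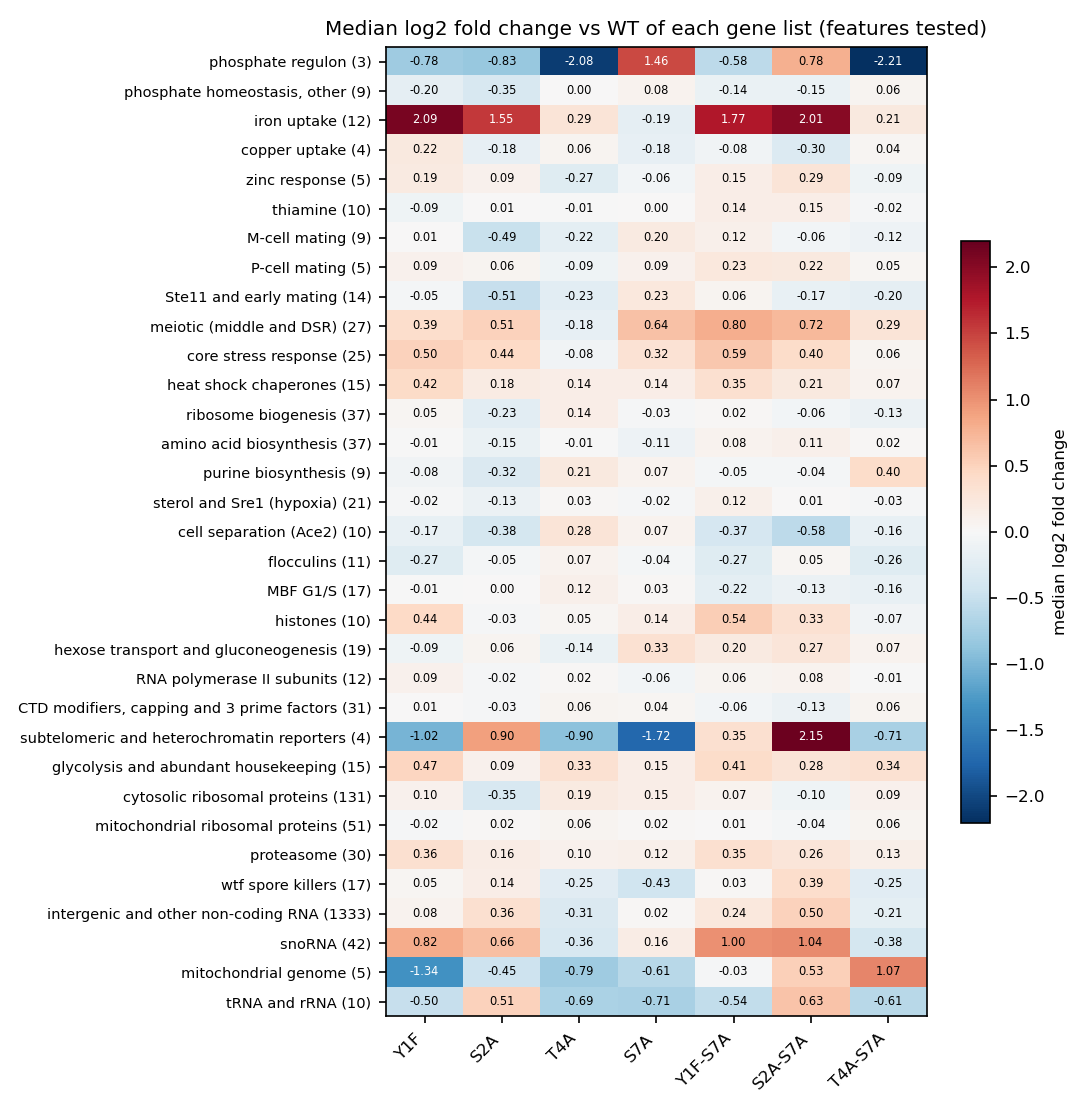
Median log2 fold change against WT of each tested gene list in the 7 mutants, with the number of tested features in parentheses (red higher, blue lower). The phosphate regulon stood at -2.08 in T4A and 1.46 in S7A, and iron uptake at 2.09 in Y1F and 1.55 in S2A.

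The double mutants against WT ask what each pair of substitutions does together. In Y1F-S7A the highest by rule were again iron uptake genes with SPNCRNA.1613: str3 at 6.68 ± 1.21 (adjusted p = 0.0075), SPNCRNA.1613 at 4.84 ± 0.38 (adjusted p = 9.0e-05), frp1 at 4.08 ± 0.57 and fip1 at 3.51 ± 0.57. The lowest by rule were SPAC11D3.11c at -4.06 ± 0.34 (adjusted p = 9.0e-05), SPAC11D3.10 at -3.99 ± 0.42, SPBC1683.04 at -3.14 ± 0.34 and hsp3104 at -2.96 ± 0.33. In all, 240 features rose and 223 fell (729 and 872 with the block). Of the fixed lists, 6 of 12 iron uptake genes rose (8 higher and 1 lower adjusted over the list alone, and adjusted p = 0.237 with an estimated correlation), as did 7 of 27 meiotic genes (9 adjusted over the list alone, and adjusted p = 0.456 with an estimated correlation) and 3 of 30 proteasome genes (8 adjusted over the list alone, 22 with the block, and with an estimated correlation adjusted p = 0.237 without the block and 0.0176 with it). Non-coding RNA features rose in 135 and fell in 26 of 1333 cases (181 and 38 adjusted over the list alone, and adjusted p = 0.272 with an estimated correlation). The phosphate gene pho1 changed by -0.58 ± 0.19 (adjusted p = 0.091, and 0.025 with the block) and pho84 by -1.15 ± 0.35 (adjusted p = 0.072, and 5.9e-05 with the block). The count of 463 became 196 without WT replicate 1, 144 without WT replicate 2, 189 without Y1F-S7A replicate 1 and 137 without Y1F-S7A replicate 2, and 19 of the 39 called features named by rule remained called in each of these fits, fip1, frp1 and shu1 among them. The str3 call was lost without WT replicate 1 or WT replicate 2 (adjusted p = 0.065 and 0.051).

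In S2A-S7A, which is h-, the highest by rule were str3 at 7.06 ± 1.22 (adjusted p = 0.0025), SPNCRNA.1613 at 5.47 ± 0.39 (adjusted p = 1.3e-05), SPNCRNA.581 at 4.52 ± 0.38 and SPNCRNA.803 at 4.41 ± 0.25. Lowest by rule were SPAC11D3.11c at -2.52 ± 0.31, SPNCRNA.1431 at -2.24 ± 0.40, SPBC1683.04 at -2.12 ± 0.32 and SPAC11D3.10 at -2.07 ± 0.38. This strain had the most changed features, 545 higher and 516 lower (1181 and 1253 with the block). With only the strains compared the order turned, with 548 called in S2A and 335 in S2A-S7A. Non-coding RNA features rose in 308 and fell in 37 of 1333 cases (349 and 51 adjusted over the list alone, and adjusted p = 0.16 with an estimated correlation). Of 12 iron uptake genes 8 rose, frp1 by 3.57 ± 0.56 and fip1 by 3.48 ± 0.57 among them (8 adjusted over the list alone, and adjusted p = 0.404 with an estimated correlation). So did 9 of 27 meiotic genes, such as rec10 by 1.87 ± 0.24 and mei4 by 1.31 ± 0.21 (10 higher and 2 lower adjusted over the list alone, and adjusted p = 0.416 with an estimated correlation), and 4 of 30 proteasome genes, such as pre8 by 0.64 ± 0.13 (4 adjusted over the list alone, 17 with the block, and adjusted p = 0.416 with an estimated correlation). Both tgp1, at 1.63 ± 0.32 (adjusted p = 0.0052), and pho1, at 0.78 ± 0.19 (adjusted p = 0.017), rose, and the pho1 call was lost without WT replicate 2 (adjusted p = 0.13) or S2A-S7A replicate 1 (adjusted p = 0.093), and the tgp1 call without WT replicate 2 (adjusted p = 0.06). Among subtelomeric reporters tlh2 rose by 4.71 ± 0.61 and SPAC212.08c by 3.25 ± 1.0, 2 of 4 (2 adjusted over the list alone). The SPAC212.08c call was lost without each of the 4 libraries (adjusted p from 0.072 to 0.23), with a change of 5.24 without WT replicate 2, and without the low-count filter (adjusted p = 0.052). The count of 1061 became 595 without WT replicate 1, 520 without WT replicate 2 and 565 without S2A-S7A replicate 2, and 29 of the 53 called features named by rule remained called without each library in turn.

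In T4A-S7A pho1 fell by 3.56 ± 0.21 (adjusted p = 8.1e-06) to 111.6 ± 7.29 CPM, and pho84 by 2.21 ± 0.36 (adjusted p = 0.0089), a call lost without WT replicate 1 (adjusted p = 0.063) or T4A-S7A replicate 2 (adjusted p = 0.1). The phosphate list thus had 2 of 3 lower (2 adjusted over the list alone, and adjusted p = 0.475 with an estimated correlation). The highest by rule were SPAC27D7.11c at 3.48 ± 0.73, ght5 at 3.41 ± 0.65, SPNCRNA.1006 at 2.75 ± 0.27 (adjusted p = 0.00041) and SPNCRNA.875 at 2.30 ± 0.34. The lowest by rule beside pho1 were SPAC11D3.11c at -3.71 ± 0.33 (adjusted p = 0.00029), SPBC1683.04 at -3.34 ± 0.34 and SPNCRNA.888 at -3.24 ± 0.28. Early mating genes fell in 4 of 14 cases: byr1 by 1.44, ste4 by 1.96, ste11 by 1.49 and mei2 by 2.09 (5 adjusted over the list alone, and adjusted p = 0.849 with an estimated correlation). Of these byr1 alone remained called without each library in turn. Of 27 meiotic genes 2 rose, spn5 by 2.57 ± 0.35 and rec10 by 1.34 ± 0.24, and spo6 fell by 1.78 (5 higher and 3 lower adjusted over the list alone). Among 1333 non-coding RNA features 28 rose and 55 fell (38 and 74 adjusted over the list alone, and adjusted p = 0.849 with an estimated correlation). In all, 71 features rose and 108 fell (347 and 355 with the block). The count of 179 became 40 without WT replicate 1, 53 without WT replicate 2, 66 without T4A-S7A replicate 1 and 52 without T4A-S7A replicate 2, and 9 of the 20 called features named by rule remained called in each of these fits, pho1, byr1 and spn5 among them.

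Each double mutant was compared with its parent to ask what S7A adds to the other substitution. In Y1F the addition changed 1 feature, SPNCRNA.952, by 1.65 ± 0.22 (adjusted p = 0.048), from 6.80 ± 0.290 to 21.3 ± 1.14 CPM. That call was lost without each of the 4 libraries in turn, when 0 features were called, and with the block 47 rose and 40 fell. An unadjusted p under 0.05 was seen for 370 features, and DESeq2 called 65, of which 66.2% were higher. The iron genes fip1, at -0.52 ± 0.51, and frp1, at -0.03 ± 0.48, did not pass (adjusted p = 1 for both).

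In S2A the addition of S7A came with a change of mating type from h+ to h-. Highest by rule were SPBC23G7.10c at 5.43 ± 0.61 (adjusted p = 0.0024), SPNCRNA.388 at 4.68 ± 0.82, mfm2 at 4.49 ± 0.47 (adjusted p = 0.0016) and SPNCRNA.1487 at 3.38 ± 0.23 (adjusted p = 4.5e-05), all 4 of them among the 6 lowest by rule in S2A against WT. By rule the lowest were SPNCRNA.609 at -1.53 ± 0.27, cnp20 at -0.88 ± 0.15, hem12 at -0.70 ± 0.11 and ubc14 at -0.70 ± 0.12, which overlaps SPAC1250.07 on 1 strand and shares reads with it. The phosphate gene pho1 rose by 1.61 ± 0.19 (adjusted p = 0.0032), from 740.9 ± 12.1 to 2261 ± 363 CPM, 1 of 3 on its list (3 adjusted over the list alone, and adjusted p = 0.522 with an estimated correlation). In all, 22 features rose and 9 fell (248 and 432 with the block), while of the 253 that DESeq2 called 45.5% were higher. The count of 31 became 2 without S2A replicate 1, 6 without S2A replicate 2, 12 without S2A-S7A replicate 1 and 8 without S2A-S7A replicate 2. Of the 12 called features named by rule, SPNCRNA.1487 alone remained called in each of these fits.

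In T4A the addition of S7A raised SPNCRNA.875 by 2.22 ± 0.34 (adjusted p = 0.029), SPNCRNA.1557 by 1.63 ± 0.22 (adjusted p = 0.02), SPNCRNA.952 by 1.56 ± 0.23, SPNCRNA.1006 by 1.55 ± 0.25 and spn5 by 2.12 ± 0.34 (adjusted p = 0.033). The lowest by rule were SPAC11D3.11c at -3.0 ± 0.32 (adjusted p = 0.0064), hsp3104 at -2.22 ± 0.32 and SPBC1683.04 at -2.09 ± 0.33. In all, 9 features rose and 3 fell (99 and 62 with the block). Without T4A replicate 1, T4A replicate 2 or T4A-S7A replicate 2 the count of 12 became 1, and without T4A-S7A replicate 1 it became 3. None of the 9 called features named by rule remained called in each of these fits. The pho1 change did not pass, at -0.60 ± 0.19 (adjusted p = 0.35).

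Interactions test whether the S7A effect in another mutant differs from its effect in WT. With T4A 1 feature was called, pho1, at -2.05 ± 0.27 (adjusted p = 0.049), which was lost without 7 of the 8 libraries in turn (adjusted p from 0.079 to 0.26). The phosphate list had 1 of 3 lower (2 adjusted over the list alone, and adjusted p = 0.276 with an estimated correlation), and tgp1 stood at -2.04 ± 0.45 (adjusted p = 0.29, and 0.019 with the block). With the block 13 interactions were positive and 11 negative, and of the 37 that DESeq2 called 43.2% were positive. With Y1F, edgeR called 0 features (47 positive and 27 negative with the block), 354 had an unadjusted p under 0.05, and DESeq2 called 62. There pho1 stood at -1.26 ± 0.27 (adjusted p = 0.16, and 0.02 with the block) and tgp1 at -1.97 ± 0.44 (adjusted p = 0.16, and 0.0095 with the block), so that 0 of the 3 phosphate genes passed (2 lower adjusted over the list alone, and adjusted p = 0.305 with an estimated correlation). Leaving out Y1F replicate 2 gave 1 feature.

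With S2A the interaction passed for 20 positive and 11 negative features (127 and 107 with the block), while of the 170 that DESeq2 called 52.9% were positive. By rule the highest were SPBC23G7.10c at 5.40 ± 0.76 (adjusted p = 0.017), nrg1 at 4.07 ± 0.77 (adjusted p = 0.046), mfm2 at 3.85 ± 0.60 (adjusted p = 0.018) and SPNCRNA.1487 at 3.57 ± 0.30 (adjusted p = 0.00048). The lowest by rule were ppk31 at -2.25 ± 0.30, SPNCRNA.952 at -2.08 ± 0.31, SPNCRNA.803 at -1.78 ± 0.32 and SPCC417.12 at -1.77 ± 0.34. Of the 11 negative interactions, 9 were of features that rose in both S2A and S7A against WT. Of these, ppk31 rose by 2.57 in S2A, 2.31 in S7A and 2.63 in S2A-S7A. In the meiotic list spn5 was 1 of 27 lower, at -2.67 ± 0.47 (6 lower and 1 higher adjusted over the list alone, and adjusted p = 0.223 with an estimated correlation). The count of 31 became 1 without WT replicate 1, 13 without WT replicate 2, 1 without S7A replicate 1, 1 without S7A replicate 2, 2 without S2A replicate 1, 2 without S2A replicate 2 and 4 without S2A-S7A replicate 2. Of the 12 called features named by rule, SPNCRNA.1487 alone remained called in each of these fits.

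Fold changes against WT were compared between mutants to ask how far their programs overlap. Every mutant is set against the same 2 WT libraries. Simulated unchanged groups therefore gave a mean correlation across features of 0.50 (highest 0.57 in 15 draws). At most 0 features were called in both groups of a pair, higher or lower, but unchanged groups hold almost no calls by design. That 0 is thus no baseline for overlaps between changed strains. The expected counts below follow from the numbers called in each strain and do not allow for the shared WT libraries, which can raise overlaps. Y1F-S7A and S2A-S7A correlated at 0.88, with 220 features higher in both (20.4 expected) and 178 lower in both (17.9 expected). S2A and S2A-S7A correlated at 0.85, with 351 higher (39 expected) and 198 lower (24.4 expected) in both, and Y1F and Y1F-S7A at 0.82, with 72 higher (3.1 expected) and 84 lower (3.7 expected). Y1F and S2A correlated at 0.62, with 59 higher (5.9 expected) and 60 lower (5 expected) in both. S7A correlated less with the double mutants that carry it, at 0.53 with Y1F-S7A, 0.44 with S2A-S7A and 0.48 with T4A-S7A. None lay above the highest simulated value, but changes particular to 1 strain lower a correlation, so this does not show a lack of sharing. The covariances were 0.186, 0.187 and 0.151 in that order, against at most 0.0756 in the simulated draws. S7A shared 35 higher and 16 lower features with Y1F-S7A (2.4 and 1.6 expected), 40 and 14 with S2A-S7A (5.4 and 3.7 expected) and 29 and 26 with T4A-S7A (0.7 and 0.8 expected). T4A and S2A correlated at 0.08, under the simulated mean, and T4A and T4A-S7A at 0.64 with 1 higher and 5 lower in both. A comparison of each mutant of a pair with a different WT library was not run.

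In the authors' deposited table, from DESeq, 38 features were higher and 72 lower in Y1F, of which edgeR called 28 and 56 in the same direction. For S2A the authors' deposited table gave 285 higher and 349 lower (269 and 234 shared), for T4A 3 and 12 (1 and 2 shared), and for S7A 47 and 55 (35 and 30 shared). For Y1F-S7A the authors' deposited table gave 92 and 100 (88 and 86 shared), for S2A-S7A 226 and 295 (213 and 258 shared) and for T4A-S7A 35 and 78 (29 and 67 shared). Against the parents the authors' deposited table gave 5 and 0 for Y1F-S7A (1 and 0 shared), 13 and 0 for S2A-S7A (10 and 0 shared) and 7 and 5 for T4A-S7A (4 and 2 shared). In these 10 comparisons 0 features were called in opposite directions, and log2 fold changes correlated across features between 0.997 and 1. The fit with the block, which calls more features, shared more of the authors' calls in the single mutants. It shared 34 higher and 67 lower in Y1F, 278 and 322 in S2A, 2 and 9 in T4A and 46 and 46 in S7A.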

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

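The tests of low expression, of wrong-strand shares, of mating type and of the silent chromosome end were chosen only after the results they address were seen; those of features without an opposite-strand neighbour and of read-through were chosen before.

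The interaction of S7A with S2A differed between backgrounds for 31 features, by a direct test of the difference. The highest by rule were SPBC23G7.10c at 5.40, nrg1 at 4.07, mfm2 at 3.85 and SPNCRNA.1487 at 3.57, and the lowest by rule were ppk31 at -2.25, SPNCRNA.952 at -2.08, SPNCRNA.803 at -1.78 and SPCC417.12 at -1.77. With T4A the difference passed for 1 gene, pho1, at -2.05, and among the single mutants 1121 features differed. The reads behind the authors' RPKM total that no listed feature holds, a quantity the comparisons do not use, made up 2.76% in S2A, 2.29% in S2A-S7A and 1.3% in Y1F-S7A, above the WT mean of 0.915 ± 0.106% (SD, n = 2); what they contain was not given.

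Opposite mating type is a candidate explanation for part of the S2A interaction. Of 10 tested features between 2114219 and 2133394 on chromosome II, the stretch of the mating-type genes, 4 were called where 0.05 were expected (Fisher's exact test, two-sided, p = 9.2e-08). The stretch was chosen after the calls were seen, and neighbouring features are not independent. This p-value therefore describes the clustering and does not test mating type. Of the 4, SPBC23G7.14 was not called in S2A against WT (0.10), and stood at -0.39 in S7A and 0.58 in S2A-S7A. For the 27 called features outside the stretch, among them the pheromone gene mfm2, mating type and the S2A substitution cannot be told apart, because S2A is the 1 h+ strain. No comparison separates these, so a biological effect of the substitution pair stays open and untested for them. The 27 differ in S2A against WT, where mfm2 stood at -4.61 while nrg1 (0.63) and cnp3 (0.13) were not called. For nrg1 and cnp3 a mating-type effect would need an opposite S2A effect of like size, which was not tested.

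The higher non-coding RNAs of S2A and S2A-S7A were set against 3 technical explanations. Low expression as the whole cause was argued against, in these libraries, by a median excess over coding features of like level. It was 0.35 (SE 0.031) in S2A and 0.27 (SE 0.028) in S2A-S7A. Each SE in this paragraph comes from resampling features, not libraries, so it does not measure the spread between the 2 replicates. Features more than 500 bases from an upstream feature on their strand had medians of 0.38 in S2A and 0.51 in S2A-S7A. Nearer features had 0.327 and 0.487. This argued against read-through that stays within 500 bases of the gene upstream as the whole cause, while longer read-through was not tested. Wrong-strand reads were first tested on features with no opposite-strand neighbour. Their median was 0.42 (SE 0.068) in S2A-S7A but 0.06 (SE 0.084) in S2A, which left S2A open. The 1092 features with such a neighbour had medians of 0.527 (SE 0.029) in S2A-S7A and 0.415 (SE 0.037) in S2A. In S2A the rise as a set was thus seen for features with an opposite-strand neighbour, not for the 241 without. A later test took the wrong-strand share from the 20 features with the fewest reads per opposite-strand read in WT. That share was 0.43% in S2A and 0.27% in S2A-S7A, against 0.079% in WT, where the choice of features makes it low. Assumed equal for all genes, it gave a median of 2.00% of the excess in S2A and 1.34% in S2A-S7A. A larger share at other genes was not tested. The excess over coding features was also above 0 in Y1F (0.156, SE 0.019) and Y1F-S7A (0.195, SE 0.021), which keep the serine that S2A removes, and whether its loss raises non-coding RNAs was not tested, with mating type and the unlisted reads of S2A not excluded in that strain.

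At the right end of chromosome I, gdt1, SPAC186.04c, SPAC186.06 and SPAC750.01 were low in S7A, with mean log2 levels against WT of -3.21 and -5.41 in its libraries, while pdc102, between gdt1 and SPAC750.01, had 28 and 10 reads in S7A against 28 and 13 in WT, and SPAC186.08c beside it 3 and 1 against 16 and 5. The low levels did not recur in the 3 double mutants. Their lowest library lay 2.88 above the higher S7A library, more than the 2.2 between the S7A libraries. This does not decide whether the S7A substitution alone is the cause, since each double mutant carries a further substitution that may act there. On their own, S2A stood at 1.97 and 1.83 and Y1F at -0.36 and -0.71. The 4 features were also taken up after their low levels in S7A were seen. Loss of the end in every cell was argued against by 16 reads of gdt1 in the lower S7A library and 97 in the other. Loss in part of the cells would lower pdc102 and SPAC186.08c alike, but features with so few reads exclude nothing, so such loss and silencing in the S7A cultures both stay open. T4A replicate 2 (-3.56) was low there where T4A replicate 1 (-0.43) was not, and nrg1 on chromosome II was low in S7A as well, at -3.38.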

How the results depend on the processing

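The alternatives below were all chosen before the data were examined. Among 252 named calls, RLE factors lost 1, no low-count filter 7, the block 3, only the strains compared 118 and DESeq2 0, and 0 reversed under any setting. Leaving out a library lost 477 of 1060 repeated calls, in 147 of the 252 results, and reversed 0. RLE and no filter kept each count within 1.5 times, except that Y1F-S7A against Y1F went from 1 to 0 under both (373 and 368 features at an unadjusted p under 0.05). RLE factors moved the median of all features by at most 0.014.

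With the replicate block the counts became 807 in Y1F, 1886 in S2A, 105 in T4A, 520 in S7A, 1601 in Y1F-S7A, 2434 in S2A-S7A and 702 in T4A-S7A against WT. Against the parents they became 87, 680 and 161, for the interactions with Y1F, S2A and T4A 74, 234 and 24, and for the joint test 2874. The block takes up the shared spread of the replicate numbers: the common dispersion went from 0.0374 to 0.0136. DESeq2 gave 438 in Y1F, 67 in T4A, 301 in S7A, 833 in Y1F-S7A and 382 in T4A-S7A, 65, 253 and 112 against the parents, 62, 170 and 37 interactions and 1765 in the joint test; the cause was not tested.

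With only the strains compared, fewer samples estimate the spread. Counts against WT then became 20 in Y1F, 548 in S2A, 0 in T4A (325 at an unadjusted p under 0.05) and 8 in S7A. In the double mutants against WT they became 181 in Y1F-S7A, 335 in S2A-S7A and 54 in T4A-S7A. Against the parents they became 0, 9 and 0, and for the interactions with S2A and T4A 12 and 0. By construction, a minimum of 2-fold lowered the counts, to 124 in Y1F, 460 in S2A, 267 in Y1F-S7A, 510 in S2A-S7A, 19 in S2A-S7A against S2A and 745 in the joint test.

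With each library left out, which removes 1 of 2 replicates, counts ran from 51 to 69 in Y1F, 379 to 473 in S2A, 2 to 6 in T4A, 17 to 37 in S7A, 137 to 196 in Y1F-S7A, 520 to 765 in S2A-S7A and 40 to 66 in T4A-S7A. They ran from 0 to 0, 2 to 12 and 1 to 3 against the parents, from 0 to 1, 1 to 26 and 0 to 3 for the interactions with Y1F, S2A and T4A, and from 672 to 990 in the joint test. Of 231 list tests against WT 54 passed; over the same 231, 0 passed with an estimated correlation, 28 with fry and 52 with the block, not all of them among the 54. Pseudocounts were not run, since they apply to normalized values.

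How far depth limits the calls was not tested. With 2 replicates, 8% of simulated 1.5-fold changes and 53.1% of 2-fold changes were recovered in Y1F, and 46% and 85.7% with the block. The simulated counts were drawn from the blocked fit, so the shares with the block assume that it holds.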

Other observations

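The tally near the ends of chromosomes I and II was chosen after the data were seen; the genes named here were chosen by rule.

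The thiamine-repressed gene nmt1, higher in S2A as given above, also rose by 3.50 ± 0.44 in Y1F-S7A and 4.04 ± 0.44 in S2A-S7A, while tnr3 fell by 0.69 and 0.88. The 10 thiamine genes as a list were not called by camera in S2A, Y1F-S7A or S2A-S7A (adjusted p = 0.966, 0.438 and 0.465), with 2 higher and 1 lower in each double mutant (the same adjusted over the list alone). The glutamate dehydrogenase gene gdh2 rose by 0.96 ± 0.21 in Y1F, 1.24 ± 0.21 in S2A, 1.43 ± 0.21 in Y1F-S7A and 2.05 ± 0.21 in S2A-S7A. In Y1F the gdh2 change was 0.55 without Y1F replicate 1 (adjusted p = 0.23), and the call was also lost without WT replicate 1 or WT replicate 2 (adjusted p = 0.093 and 0.24). The galactose gene gal10 rose by 1.77 ± 0.29 in S2A and 1.96 ± 0.29 in S2A-S7A. In S2A-S7A the polymerase subunit genes rpb4 and rpb7 rose by 0.47 ± 0.14 and 0.44 ± 0.13, and the 3 prime factor gene rhn1 fell by 0.88. The rpb4 and rpb7 calls were lost without each of the 4 libraries in turn, as was that of tnr3 in Y1F-S7A.

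Flocculin gene pfl7 fell in each of Y1F, S2A, Y1F-S7A and S2A-S7A, by 4.33, 2.18, 2.93 and 1.94 (and by 2.47 in T4A-S7A), while pfl9 fell by 1.65 in Y1F and rose by 1.25 in S2A-S7A. The stress gene gst1 fell by 4.09 in S2A, 1.91 in Y1F-S7A and 2.93 in S2A-S7A. Among snoRNA features sno12 rose by 1.38 ± 0.29 in Y1F, 1.19 ± 0.29 in Y1F-S7A and 1.13 ± 0.29 in S2A-S7A, and others, such as snR95 and snR3, lie almost wholly inside another feature, so their reads are uncertain. The calls of sno12 and pfl9 named here were each lost without some library, as were those of gst1 in Y1F-S7A and pfl7 in S2A-S7A. In S7A a 17-member group of wtf genes had a median of -0.43 with 0 genes called (2 lower adjusted over the list alone); camera with BH adjustment called the list at the preset correlation (adjusted p = 0.00167) and not at an estimated one (adjusted p = 0.406).

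Within 100 kb of the ends of chromosomes I and II lay 107 tested features (chromosome III was not tallied). In S2A 22 of them rose and 7 fell (7.7 and 5 expected from all features), in S2A-S7A 34 rose and 3 fell (9.1 and 8.6 expected), and in Y1F 3 rose and 12 fell (1.4 and 1.8 expected). In Y1F-S7A 7 rose and 7 fell (4 and 3.7 expected), in T4A-S7A 1 rose and 8 fell (1.2 and 1.8 expected), in S7A 1 rose and 5 fell (1.1 and 0.8 expected) and in T4A 0 rose and 2 fell (0 and 0.1 expected). Their median change was -0.50 in Y1F, 0.59 in S2A, -0.56 in T4A, -0.39 in S7A, 0.03 in Y1F-S7A, 0.91 in S2A-S7A and -0.50 in T4A-S7A. No explanation was tested.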
